A study of Arabidopsis thaliana with 8 samples.

How the data were processed

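Arabidopsis thaliana plants of ecotype Columbia-0 were compared at 2 ages, 1 week and 4 weeks, with 4 samples of total RNA per age. The age and the number of each sample were taken from the labels. The deposited table holds an array intensity on a linear scale for 3439 rows and 8 samples. How the authors scanned, background-corrected and scaled these intensities is not given in the sources used here. The values themselves are never below 0, have similar sums in all samples, hold exact 0s and end at a ceiling of 100 that several rows share. Of the values above 0, 81.0% were under 1. No column of other samples was present.

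Rows were named with the GEO annotation of the array platform, updated through gene numbers with a reference gene table of the Arabidopsis genome (an assembly of the TAIR release). Of the rows, 692 name 1 gene, 870 name several and 1877 are unnamed here, and 690 of the 692 were found in the reference table. No gene was named from a row with several genes. Where the reference symbol is only a locus code, which held for 11 of the listed genes, the common short name from the list is given beside it. The genome build of the array design is not given in the sources used here, so no coordinates are printed.

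Values were put on the log2 scale with 0 as missing. The medians of the arrays differed by up to 0.13 on that scale, above the limit of 0.1 set before the data were examined, so the arrays were quantile normalized. A row needed 3 measured samples in each age. This left 2924 rows, 588 of which name 1 gene, and 515 rows were not tested, among them 222 at 0 in every sample. Also left out were 2 rows at the ceiling in all 8 samples, a step that was decided after seeing the data. Each row was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 as 4 weeks minus 1 week, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences, standard errors and folds come from this fit, while the signals printed with an SD are the deposited values with 0s included. For a row at the ceiling in all samples of an age, the fold of the deposited log2 means, with the ceiling at its value, is given as a lower bound. Quantile normalization gives the rows tied at the ceiling of a sample 1 shared value, so the fold on the normalized scale is not a bound.

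Named genes followed a rule set before the data were examined. Among called single-gene rows whose ages did not overlap, it takes the 6 largest rises and the 6 largest falls. From a gene list with 5 or more tested members whose set test passes, it takes the 3 largest changes in the direction of the list and the largest in the other direction, and from one whose set test does not pass, the member with the largest change. From each shorter list it takes every member past the threshold. The listed genes that did not pass are printed in addition, so that every listed gene is accounted for. A list was tested as a set, against all other single-gene rows measured in all samples, by camera with a preset correlation of 0.01 and with an estimated correlation. It was also tested against no change, without other genes, by fry and by an exact two-sided permutation test of the list mean over 70 assignments, whose smallest p is 0.0286. A test against no change can pass for a list that moved no more than other genes. Another 4 lists, drawn after the gene names and some values had been seen, are reported as observations only.

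The fit has no block, as set before the data were examined, because the labels give shared numbers without saying what they mean. Deviations from the age means of same-numbered samples of the 2 ages correlated at 0.425 to 0.527 in all 4 pairs. Samples of other numbers correlated at 0.180 to 0.397 within numbers 1 and 2 and within numbers 3 and 4, and at −0.419 to −0.351 between them. By a rule of correlations over 0.1 in every pair, the numbers were taken to pair the samples, and the fit with the number as a block is given where it changes a call. This pairing comes from the data, not from the labels. Samples of other numbers within numbers 1 and 2, and within numbers 3 and 4, also correlated at over 0.1. The rule therefore cannot tell pairing by number from a likeness within these groups. The values themselves were higher for the same number. In numbers 1 and 2 they were 0.503 and 0.527, against 0.180 and 0.229 for the other number, which argues against a likeness of the group alone there. In numbers 3 and 4 the gap was small, with 0.425 and 0.433 against 0.343 and 0.397. No 2 samples shared identical values. The first principal component (61.2% of the variance) separated the ages and the second (19.8%) separated samples 1 and 2 from samples 3 and 4. No label explains the latter, so alternatives that treat these pairs of samples as a block, a random effect (with statmod 1.5.0) or repeats were added after seeing the data.

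Alternatives set before the data were examined were the values as deposited, median centring, leaving out the tercile of rows with the lowest signal, the sample number as a block, rows measured in all 8 samples, a variance trend with robust estimation, array weights, other thresholds, an exact permutation test per row and leaving out each sample in turn. A pseudocount of 0.0777, the 5th percentile of the values above 0, and leaving out rows at the ceiling were added later.

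The tests were tested on simulated data with the spread of the 2814 rows measured in all samples. With 4 independent samples per age, 22.0% of 50 rows changed 1.5-fold were recovered, 68.0% at 2-fold, 98.0% at 4-fold and 100.0% at 8-fold, and 6 of 2614 unchanged rows were called. With no age effect but shared deviations of samples 1 and 2, and of samples 3 and 4, within each age, the fit of 8 samples called 26 of 2814 rows and the fit of averaged pairs called 0. No row changed with age in that simulation, which makes the adjustment stricter than in the real data. Its deviations were also independent between the ages, whereas those of the real samples correlated. The 26 rows therefore do not show how many real calls shared deviations could make. For lists of 5 genes, camera passed in 5 of 100 draws without a change and in 100 of 100 with a 2-fold change. In these draws no gene outside the list changed, whereas many did in the real data. Camera may therefore miss a 2-fold change of a list in the real data. Figures were drawn with matplotlib 3.10.9.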

Results

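Transcript levels were measured in wild-type Arabidopsis thaliana plants of the Columbia-0 ecotype, a standard laboratory accession of thale cress, at ages of 1 week and 4 weeks. Total RNA of each sample gave 1 array signal for each of 3439 rows, and each age had 4 samples numbered 1 to 4. The deposited signals are in arbitrary units whose scale is not given in the sources used here. Their sum per sample ran from 3070 to 3374, their median from 0.390 to 0.453, and between 11.3% and 13.6% of the rows of a sample were listed at exactly 0. The 10 brightest rows made up at most 25.2% of a sample's summed signal. The labels state neither which organs were taken nor whether the samples of an age came from separate plants, so the p-values below measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

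The comparison between the ages asked which transcripts differed in level between 1-week-old and 4-week-old plants. Among rows naming a single gene whose samples did not overlap between the ages, the largest rise was that of AT2G26110. Its deposited signal was 0.0333 ± 0.0323 at 1 week and 0.684 ± 0.200 at 4 weeks (SD, n = 4), a normalized log2 difference of 3.96 (SE 0.49, limma adjusted p = 0.000594), with a signal above 0 in 3 of the 4 samples of 1-week-old plants. AT2G37750 rose from 0.0518 ± 0.0374 to 0.533 ± 0.0621 (log2 difference 2.81, SE 0.22, limma adjusted p = 7.35e-05), again with 3 of the 4 younger samples above 0. The value at 0 was left out of the log2 mean of both genes, so their fold understates the difference of the deposited means. AT3G04210, which encodes a TIR-NBS protein of the class of plant disease resistance proteins, rose 5.39-fold (log2 difference 2.43, SE 0.28, limma adjusted p = 0.000230). Smaller rises were those of AT4G38490 (log2 difference 1.74, SE 0.25), of the radical SAM family gene AT2G39670 (1.85, SE 0.47) and of the type IA DNA topoisomerase gene AT4G31210 (1.78, SE 0.51).

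The largest fall was that of AT1G06510, a gene for a protein with a forkhead-associated domain. Its signal was 1.74 ± 0.528 at 1 week and 0.144 ± 0.0177 at 4 weeks (SD, n = 4), 12.4-fold lower in the older plants (log2 difference −3.63, SE 0.19, limma adjusted p = 4.53e-06). AT4G20300 went from 3.06 ± 0.251 to 0.306 ± 0.0448, which was 10.1-fold lower (log2 difference −3.34, SE 0.12, limma adjusted p = 1.08e-06). AT5G05400, which encodes a disease resistance protein with a nucleotide-binding site and leucine-rich repeats, was 8.26-fold lower at 4 weeks (SE 0.15 on the log2 scale, limma adjusted p = 3.61e-06). The pair of resistance-type genes AT3G04210 and AT5G05400 thus moved in opposite directions. AT5G66050, the copper transport family gene AT4G05030 and AT5G52530 were 9.27-fold, 8.57-fold and 8.21-fold lower at 4 weeks, with limma adjusted p of 0.000108, 4.58e-05 and 7.35e-05. The plot gives the samples behind these 12 genes, which were taken from rows without overlap between the ages.

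**Figure D1:**
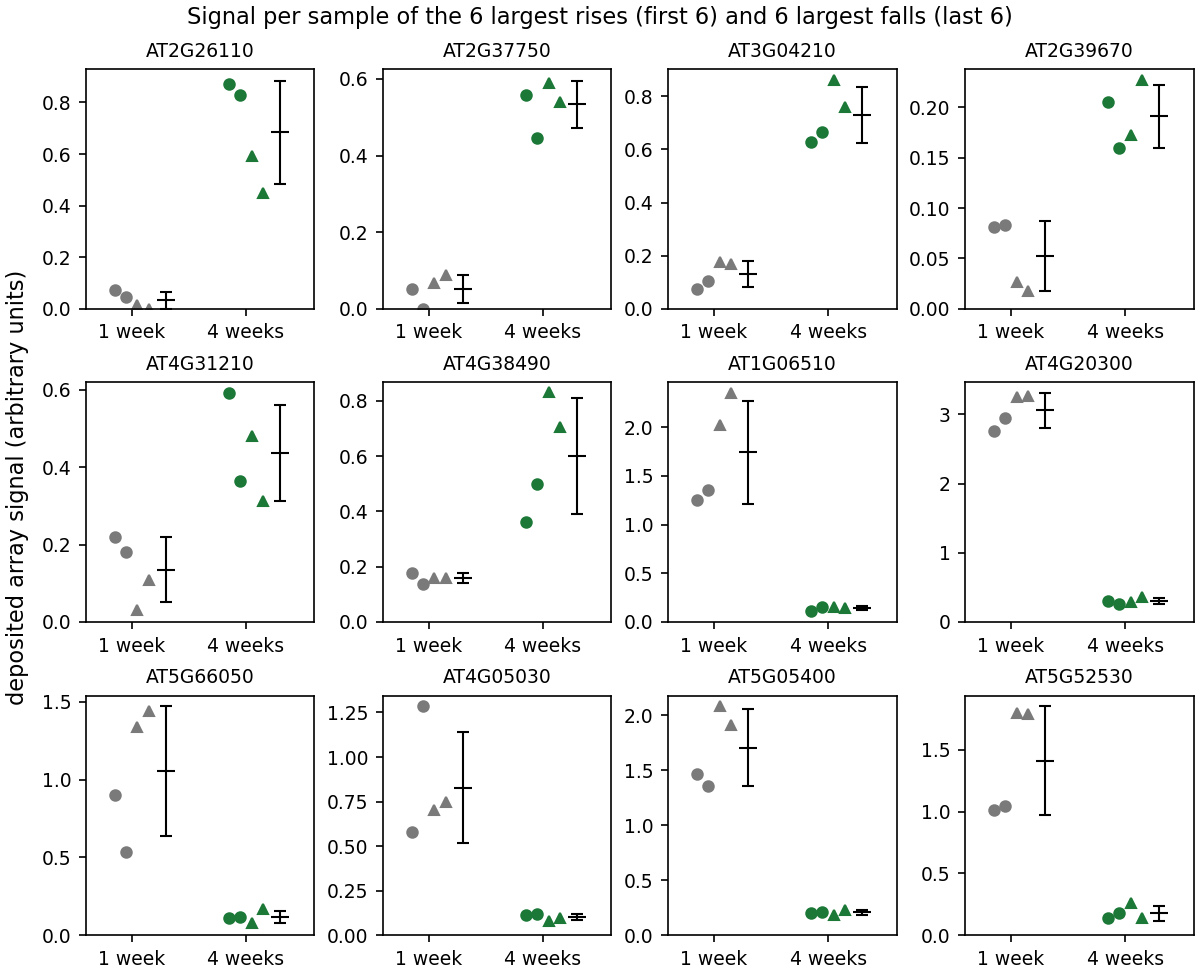
Deposited array signal (arbitrary units, linear axis from 0) of each of the 8 samples for the 6 largest rises and the 6 largest falls among single-gene rows. Circles are samples 1 and 2, triangles samples 3 and 4, grey is 1 week and green 4 weeks, and the black bars are the mean ± SD of the 4 samples. AT4G20300 lies near 3.06 in the younger and near 0.306 in the older plants.

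For AT2G39670 and AT4G31210 the call depended on the way samples 1 and 2, and samples 3 and 4, were treated. With these pairs of samples averaged before the fit, an alternative chosen after seeing the data, their limma adjusted p was 0.118 and 0.105, and it was 0.0165 and 0.00741 in the same averaged fit with the pairs as a block. Over all alternatives it ran from 0.00463 to 0.118 for AT2G39670 and from 0.00741 to 0.132 for AT4G31210. The size of these rises depended on the samples too. The log2 difference of AT2G39670 was 0.97 in samples 1 and 2 alone and 2.74 in samples 3 and 4 alone, and over all alternatives it ran from 0.88 to 2.74, and that of AT4G31210 from 1.19 to 2.36. AT4G31210 also missed the threshold without 4-week sample 1 (0.0596) or without 4-week sample 3 (0.0516). The other 10 genes stayed past the threshold under every limma alternative that tested them, while in the exact permutation test per row 0 of 2814 rows passed after adjustment. Without the tercile of rows with the lowest signal, only the falls of AT1G06510, AT4G20300, AT5G05400 and AT5G52530 were tested. All the named rises lay in that tercile. Over the alternatives that tested them, the log2 difference ran from 2.65 to 4.23 for AT2G26110 and from 2.17 to 2.97 for AT2G37750.

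Across the array, 1337 of 2924 tested rows (45.7%) differed between the ages at a limma adjusted p under 0.05, of which 741 were higher and 596 lower at 4 weeks. Differences of 2-fold or more made up 599 of these, with 261 higher and 338 lower, and differences of 4-fold or more were 32 rises and 105 falls. Of the called rows, 262 name a single gene, 142 of them higher and 120 lower at 4 weeks. The called share was 40.0% in the tercile of rows with the lowest signal, 46.5% in the middle tercile and 50.7% in the tercile with the highest signal. In 1318 tested rows (45.1%) every measured sample of 1 age lay above every measured sample of the other, with signals of 0 left out. The median log2 difference over all tested rows was 0.16, with quartiles of −0.40 and 0.58. When rows at 0 were kept by adding a pseudocount, it was 0.03 over 3437 rows, of which 222 were at 0 in every sample. The pseudocount also draws the differences of dim rows toward 0.

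**Figure D2:**
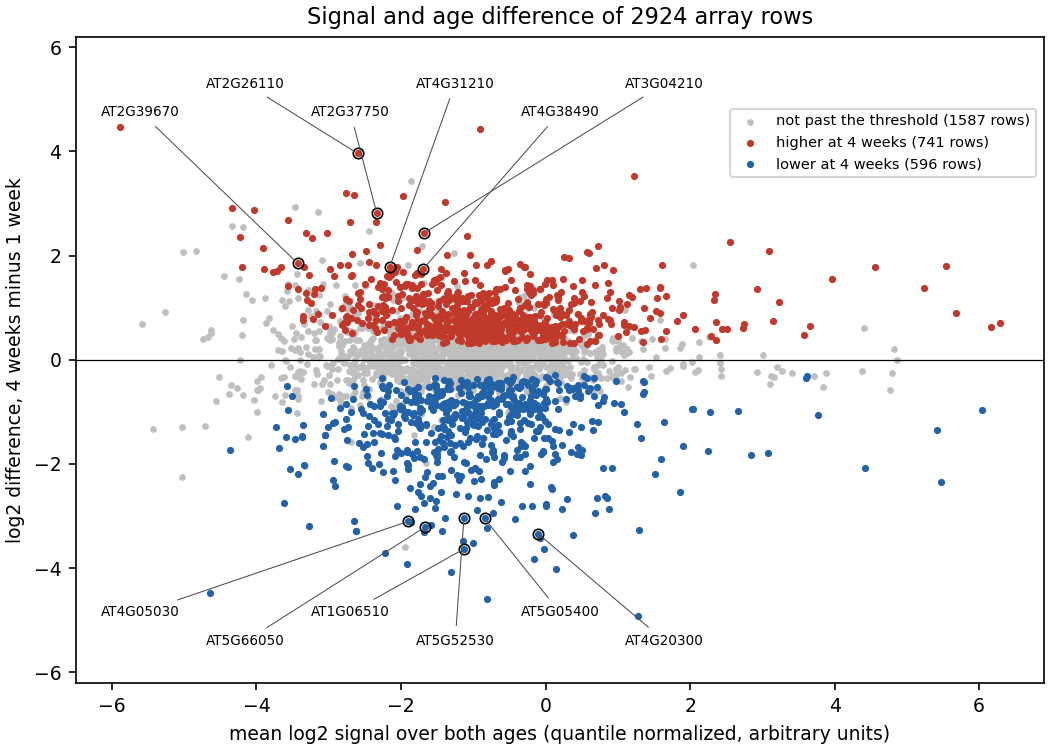
Log2 difference between the ages (4 weeks minus 1 week, vertical axis) against the mean log2 signal over both ages (quantile normalized, arbitrary units, horizontal axis) for 2924 rows. Each point is 1 row, red where it was higher (741) and blue where it was lower (596) at 4 weeks at adjusted p under 0.05, and grey otherwise, with the 12 genes named above circled. Called rows occur at all signal levels.

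Within each age, samples 1 and 2 resembled each other, as did samples 3 and 4. The median correlation across rows was 0.948 within such a pair of samples and 0.879 between samples of different pairs of the same age, against 0.723 and 0.674 across ages. Averaging each such pair to 1 value per age, which leaves 2 values against 2, reduced the calls from 1337 to 400, of which 145 were higher and 255 lower at 4 weeks, and 398 of the 400 were among the 1337. The same averaged values with the pairs as a block, so that samples 1 and 2 of one age are set against samples 1 and 2 of the other, gave 1060 calls, 550 higher and 510 lower, 932 of them among the 1337. This blocked fit leaves 1 residual degree of freedom per row, so its calls lean on the variance that eBayes shares between rows. A random effect for each pair gave 727 calls, 322 higher and 405 lower. Samples 1 and 2 of both ages alone gave 1273 calls, samples 3 and 4 alone 1414, and a fit of all 8 samples with these pairs as a block 1692. The fits of samples 1 and 2 alone, and of samples 3 and 4 alone, use only the spread within a pair. Deviations shared by a pair can count as age differences in them. The direction in samples 1 and 2 was that in samples 3 and 4 for 81.5% of all tested rows and for all of the 1337 called rows, which were selected on both. A test of the difference between these effects called 9 of 2814 rows by limma at adjusted p under 0.05 and 555 at unadjusted p under 0.05.

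**Figure D3:**
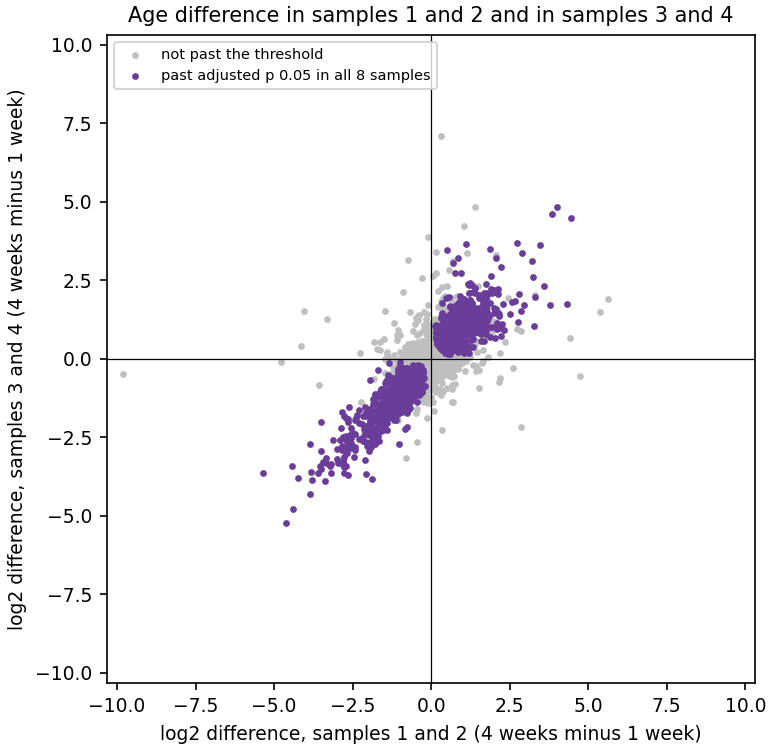
Log2 difference between the ages (4 weeks minus 1 week) in samples 3 and 4 (vertical axis) against that in samples 1 and 2 (horizontal axis), on the same scale, each point being 1 row. Purple points are the rows past adjusted p 0.05 in the fit of all 8 samples, and all 1337 of them, selected on both axes together, have the same sign on both, against 81.5% of all tested rows; the correlation across rows, which are not independent replicates, was 0.785.

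Of 26 gene lists fixed before the data were examined, with 492 genes in all, 22 genes were on the array as single-gene rows and 20 could be tested. Of these 20 genes, 5 rose, 2 fell and 13 did not pass the threshold, and the same number, 7, passed when adjusted over the list alone, that is over all 20 listed genes. Phosphoribulokinase (PRK), the Calvin cycle enzyme that makes the acceptor of CO2, went from 0.954 ± 0.134 at 1 week to 2.01 ± 0.175 at 4 weeks (SD, n = 4), a rise of 1.14 on the log2 scale (SE 0.12, limma adjusted p = 0.000163) that passed under every limma alternative. Both measured genes of chlorophyll synthesis rose, namely CHLM, for magnesium protoporphyrin IX methyltransferase (log2 difference 0.38, SE 0.10, limma adjusted p = 0.0156), and AT1G74470, for geranylgeranyl reductase (CHLP; 0.54, SE 0.16, limma adjusted p = 0.0237). The photosystem I subunit gene PSAN rose by 0.39 (SE 0.13, limma adjusted p = 0.0389). With samples 1 and 2, and samples 3 and 4, averaged, the adjusted p of CHLM, AT1G74470 and PSAN was 0.264, 0.231 and 0.275, and 0.186, 0.0860 and 0.190 with the averaged pairs as a block, and over all alternatives it ran from 0.00215 to 0.264, from 0.00103 to 0.231 and from 0.0237 to 0.275.

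The rise of PSAN was also lost on the values as deposited (0.26, limma adjusted p = 0.176) and after median centring (0.21, 0.239), and without any 1 of 1-week samples 1, 3 and 4 (adjusted p 0.0821, 0.0959 and 0.0543) or 4-week samples 2, 3 and 4 (0.0755, 0.0869 and 0.0877). AT1G74470 missed the threshold without 1-week sample 3 or 4 (0.0603 and 0.0583) or 4-week sample 1 or 2 (0.0631 and 0.0599). Its direction and that of PSAN were the same throughout.

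The other photosynthesis genes did not pass the test without a block. The photosystem II genes PSBW, PSBY and PSB27 had log2 differences of 0.60 (SE 0.32, limma adjusted p = 0.158), 1.09 (SE 0.83, 0.314) and 0.89 (SE 0.46, 0.146), and the light-harvesting gene LHCB1.5 (AT2G34420) had −0.46 (SE 0.23, 0.135). With the sample number as a block, all 4 passed, at adjusted p of 0.0286, 0.00117, 0.00923 and 0.0139. In the fit of averaged pairs with the pairs as a block, PSBY and PSB27 passed (0.0107 and 0.0325) and PSBW and LHCB1.5 did not (0.0945 and 0.126), and over all alternatives the adjusted p ran from 0.00748 to 0.935 for PSBW, from 0.000987 to 0.567 for PSBY, from 0.00675 to 0.364 for PSB27 and from 0.00794 to 0.370 for LHCB1.5. PSBW also passed without 1-week sample 2 (0.0474) and PSB27 without 4-week sample 1 (0.0425). The log2 difference of PSBY was 0.62 without 1-week sample 1, and over all alternatives the differences ran from 0.04 to 0.92 for PSBW, from 0.62 to 1.54 for PSBY, from 0.56 to 1.24 for PSB27 and from −0.99 to −0.27 for LHCB1.5. Normalization changed the differences of the bright rows of LHCB1.5 and PSBW. LHCB1.5 had a deposited signal of 12.9 ± 2.85 at 1 week and 6.68 ± 1.34 at 4 weeks (SD, n = 4), a log2 difference of −0.94 on the values as deposited (limma adjusted p = 0.00901), while PSBW had deposited signals of 21.2 ± 8.38 and 21.8 ± 6.06 and a log2 difference of 0.09 on that scale.

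Both measured genes of amino acid synthesis fell, and both act in the synthesis of branched-chain amino acids. AT3G23940, for dihydroxyacid dehydratase (DHAD), went from 0.830 ± 0.0585 to 0.391 ± 0.0268 (SD, n = 4), 2.19-fold lower at 4 weeks (log2 difference −1.13, SE 0.10, limma adjusted p = 5.79e-05), and passed under every limma alternative. AT3G58610, for ketol-acid reductoisomerase (KARI), had a log2 difference of −0.70 (SE 0.22, limma adjusted p = 0.0296) with overlapping samples. Its adjusted p was 0.180 with samples 1 and 2, and samples 3 and 4, averaged, and 0.0511 with these averaged pairs as a block, and over all alternatives it ran from 0.00982 to 0.180. KARI also missed the threshold without 1-week sample 1 (0.0614), 2 (0.0576) or 4 (0.0703) or 4-week sample 3 (0.0687) or 4 (0.0623).

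Of 5 tested genes for proteins of the plastid ribosome, 1 rose and 4 did not pass. The riser was AT5G65220, for ribosomal protein L29 (PRPL29; log2 difference 0.65, SE 0.15, limma adjusted p = 0.00756). Its adjusted p was 0.159 with samples 1 and 2, and samples 3 and 4, averaged, and 0.0738 with these averaged pairs as a block, and ran from 0.00349 to 0.159 over all alternatives. The other 4 had log2 differences between 0.04 and 0.18. Over all alternatives these ran from −0.31 to 0.47 for AT3G54210 (PRPL17) and from −0.25 to 0.58 for AT1G29070 (PRPL34). They ran from −0.04 to 0.20 for AT4G01310 (PRPL5) and from 0.03 to 0.33 for AT3G13120 (PRPS10). As a set, the 5 genes had a mean log2 difference of 0.22. They did not differ by camera from the rest of the 563 named genes measured in all samples, a number that includes the 5 (p = 0.449, and p = 0.469 with an estimated correlation). Tested against no change rather than against other genes, the list mean gave p = 0.314 in an exact two-sided permutation test, and fry gave p = 0.0326. This was the only list with 5 tested genes.

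The remaining listed genes did not pass the test without a block. In plastid fatty acid synthesis, AT1G24360, for ketoacyl reductase (FABG), had a log2 difference of −0.25 (SE 0.11, limma adjusted p = 0.107; 0.0313 after median centring, and from 0.0313 to 0.531 over all alternatives) and the thioesterase gene FATB 1.18 (SE 0.99, 0.354). The value of FATB depended on single samples, with 0.46 without 1-week sample 2 and 2.08 without 1-week sample 4, and was 2.18 in samples 1 and 2 alone (0.0177) and 0.18 in samples 3 and 4 alone (0.860), within a range of adjusted p from 0.0177 to 0.860 over all alternatives. Among antioxidant enzymes, AT3G52960, for peroxiredoxin IIE (PRXIIE), had 0.41 (SE 0.30, 0.291), and it passed with the sample number as a block (0.0130) but not in the fit of averaged pairs with the pairs as a block (0.159), with a range from 0.00415 to 0.532 over all alternatives. The thioredoxin reductase gene NTRC had 0.01 (SE 0.16) and the ATP sulfurylase gene APS4 0.09 (SE 0.20). For 16 lists, which include root, flower and seed markers, cell division and senescence, no gene was on the array as a single-gene row, so the organ makeup of the samples was not checked.

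Rows listed at 0 do not show that a transcript was absent, since SBPASE, for a Calvin cycle enzyme of leaves, was listed at 0 in 6 of 8 samples and AT1G64510, for plastid ribosomal protein S6 (PRPS6), in all 8. In 2 rows all samples of 1-week-old plants were listed at 0 and all samples of 4-week-old plants were above 0. The 1 named gene among them, AT4G12270, named after its values were seen, had a mean of 0.406 ± 0.301 (SD, n = 4) at 4 weeks. In 3 rows the reverse held. At the other end of the scale, 7 rows reached the highest value in the table, a ceiling of 100, in at least 1 sample. One unnamed row lay at the ceiling in all 4 samples of 1-week-old plants. Its deposited signal was there at least 5.92-fold that at 4 weeks (17.9 ± 6.92), and the normalized fold was 5.11 (limma adjusted p = 0.000130). Another unnamed row lay at the ceiling in all 4 samples of 4-week-old plants. Its deposited signal was there at least 1.94-fold that at 1 week (52.6 ± 12.1), and the normalized fold was 1.63 (limma adjusted p = 0.0244).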

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

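The alternatives that treat samples 1 and 2, and samples 3 and 4, in pairs, the pseudocount and leaving out rows at the ceiling were chosen after the data were seen. The count of 1337 rows stayed within 1.5 times under both other scalings (1403 as deposited, 1349 after median centring), without the lowest tercile (1022 of 1949), without any 1 sample (1074 to 1279), and with a pseudocount of 0.0777 (1268 of 3437). In the exact permutation test per row, 1285 of 2814 rows had the smallest p that 70 assignments allow, 0.0286, and 0 rows passed after adjustment, where the smallest adjusted p was 0.0626. With the sample number as a block, the pairing raised it to 1656, of which 1311 were among the 1337, and added calls of PSBW, PSBY, PSB27, LHCB1.5, PRXIIE, AT5G39980, AT3G26630, AT2G46050 and AT1G62150, changing no other call of a gene or list named here. Of these, PSBY and PSB27 alone also passed with the averaged pairs as a block, where AT5G39980, AT3G26630, AT2G46050 and AT1G62150 had adjusted p of 0.177, 0.236, 0.115 and 0.109. Averaged pairs of samples left 400 calls (145 higher, 255 lower), while the same averaged values with the pairs as a block gave 1060 (550 higher, 510 lower), against 1692 for all 8 samples with that block. A random effect of these pairs gave 727 (322 higher, with an estimated correlation of 0.621). The cause was not tested. Stricter thresholds keep fewer rows by construction: 599 (261 higher, 338 lower) with 2-fold or more, and 833 (376 higher) at adjusted p under 0.01. The plastid ribosomal list passed only with fry (mean log2 difference 0.22, p = 0.0326; exact permutation p = 0.314), and its mean ran from 0.11 to 0.34 over the alternatives. AT4G09620 went from −0.32 to 0.39 (adjusted p = 0.0381) with samples 1 and 2 alone and to −1.03 (adjusted p = 0.00714) with samples 3 and 4 alone; the cause was not tested. Over all named and listed genes, 1422 comparisons of an alternative with the reported value kept the call, 68 lost a call and 67 gained one. Those that kept the call include changes of direction where neither value passed, as for AT3G22150 on the values as deposited. The planned pseudocount was not run, because the 5th percentile of all values is 0. Signals of 0 and at the ceiling limit what can be measured, and the brightest 50 rows had a median log2 difference of −0.61 as deposited and −0.21 after quantile normalization.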

Other observations

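The gene families described next, and the tests of the scaling of whole arrays, of shared preparations, of splits that part the numbered pairs and of dividing cells, were chosen only after results had been seen. Of 16 tested genes for pentatricopeptide repeat proteins, which bind and process organelle RNA, 5 rose, 2 fell and 9 did not pass. The risers were AT5G15280 (log2 difference 1.61, SE 0.13, limma adjusted p = 3.74e-05), AT2G19280 (1.24, SE 0.15), AT1G31790 (1.00, SE 0.21), AT1G79080 (0.90, SE 0.12) and AT4G21170 (0.67, SE 0.14). CRR21, a factor for the plastid NDH complex, fell (−1.43, SE 0.23, limma adjusted p = 0.00141), as did AT3G51320 (−0.43, SE 0.12). The list mean was 0.38, above the named genes without passing camera (p = 0.0876, and p = 0.192 with an estimated correlation), and it was 0.18 (camera p = 0.339) without the tercile of rows with the lowest signal. Against no change, fry gave p = 0.000240 and the exact permutation test the smallest p it allows, 0.0286. Fry gave p under 0.05 for every list tested here. With 45.7% of all tested rows called, such a result does not set a list apart from other genes. With samples 1 and 2, and samples 3 and 4, averaged, AT5G15280 and AT2G19280 stayed past the threshold and the other 5 did not, with adjusted p of 0.0580 to 0.255. With these averaged pairs as a block, AT4G21170 (0.0519) and AT3G51320 (0.170) did not pass and the other 5 did. With the sample number as a block, AT5G39980 (0.0416) and AT2G46050 (0.0220) passed in addition as rises and AT3G26630 (−0.34, 0.0309) as a fall. The call of AT3G26630 depended on the processing, with −0.84 (0.000858) on the values as deposited and −0.89 (0.000817) after median centring. On the quantile normalized values it lay near the threshold (0.0509). It passed there without the lowest tercile (0.0371), in rows measured in all 8 samples (0.0496), with a variance trend and robust estimation (0.0365) and without 4-week sample 1 (0.0385). AT3G49740 (1.44, limma adjusted p = 0.0583) passed as a rise on the values as deposited (0.0197), after median centring (0.0251) and with the averaged pairs as a block (0.0380). It also passed with array weights (0.0314) and without 1-week sample 3 (0.0225). Its log2 difference was 2.34 in samples 1 and 2 alone and 0.54 in samples 3 and 4 alone. AT3G51320 also missed the threshold without 1-week sample 3 or 4 (both 0.0535) or 4-week sample 4 (0.0518).

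Of 7 genes for mTERF proteins, organelle nucleic acid binding proteins, AT1G79220 fell (log2 difference −0.96, SE 0.15, limma adjusted p = 0.00106) and 6 did not pass. The list mean of −0.21 did not pass camera (p = 0.278, and p = 0.335 with an estimated correlation), with fry at p = 0.0139 and the exact permutation test at 0.0286, the smallest p it allows. The mean was −0.09 with samples 1 and 2 alone and −0.34 with samples 3 and 4 alone, and did not pass camera in either. With the sample number as a block, AT1G62150 of this list passed as a rise (0.61, 0.0430), against the direction of the list mean. It also passed without 1-week sample 1 (0.0351) or 2 (0.0472). Its log2 difference was 0.22 in samples 1 and 2 alone and 1.00 in samples 3 and 4 alone. Among 8 accessory factors of the photosynthetic complexes and of the plastid NDH complex, LPA19, an assembly factor of photosystem II, rose (1.04, SE 0.16, limma adjusted p = 0.00112), PIFI (−0.37, SE 0.10, 0.0149) and AT1G74730 (−1.42, SE 0.23, 0.00133) fell, and 5 did not pass. Their mean of 0.17 turned to −0.01 without the lowest tercile of rows, and camera gave p = 0.582 (p = 0.590 with an estimated correlation; fry p = 0.0211; exact permutation p = 0.0286). CCB3 of this list passed as a rise on the values as deposited (0.0302) and after median centring (0.0435). PSB27 of this list was also on a list fixed before. With pairs of samples averaged, AT1G79220, LPA19, PIFI and AT1G74730 did not pass, at adjusted p of 0.0644, 0.0696, 0.281 and 0.0590. With the averaged pairs as a block, AT1G79220 (0.0177), LPA19 (0.0108) and AT1G74730 (0.00536) passed and PIFI did not (0.196).

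A list of 7 genes for histone H3, mitotic kinesins and the cell cycle protein FBL17 was used to ask whether older plants may hold fewer dividing cells. The list mean was 0.0692 on the log2 scale (camera p = 0.656, and p = 0.677 with an estimated correlation, fry p = 0.0274, exact permutation p = 0.229). It was −0.01 after median centring and 0.21 without the tercile of rows with the lowest signal, so the question stays open. This reading was set after the result: as first stated, a list mean of 0 or above, or a camera p of 0.05 or more, counted against fewer dividing cells, and by that rule the list counted against them. The histone H3 gene AT5G65360 rose (0.98, SE 0.10, limma adjusted p = 0.000161), with 5 genes not past the threshold, while FBL17 fell (−0.79, SE 0.24, 0.0295), a call lost without 1-week sample 3 (0.0717) or 4 (0.0693) or 4-week sample 1 (0.0744) or 2 (0.0694). The call of FBL17 was also lost on the values as deposited (0.0536), with samples 1 and 2 alone (0.0669), with pairs of samples averaged (0.190) and with a random effect of the pairs (0.0992), and it passed with the averaged pairs as a block (0.0284). AT1G13370, also for histone H3, had −0.13 (adjusted p = 0.486), and −0.62 on the values as deposited (0.00474). Histone H3 genes are nearly identical in sequence, so an array row may measure several of them.

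Falls of 4-fold or more outnumbered rises, with 105 against 32 (76.6% falls; exact two-sided binomial p = 2.88e-10, over rows that are not independent). These technical explanations were tested. Values near the floor are argued against by the tercile of rows with the highest signal, where falls made up 84.2% (32 against 6, exact binomial p = 2.43e-05). In a fit with a pseudocount, which keeps rows at 0, falls made up 84.9% (73 against 13). A pseudocount also shrinks the changes of dim rows, and the lowest tercile held 21 of the 32 rises and 39 of the 105 falls. This fit therefore cannot decide whether the omission of rows at 0 made falls exceed rises. The quantile normalization applied here is argued against as the cause by the values as deposited (72.4%, 97 against 37) and by median centring (75%). The authors' own scaling, which is not known, is part of all these values, so this test cannot address it. That strong falls with age exceed strong rises remains a hypothesis, with cross-hybridisation and differences in organs between the ages untested.

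Samples 1 and 2 resembled each other within each age, as did samples 3 and 4. Noise of dim rows is argued against by the tercile of rows with the highest signal, where the median difference between these pairs of samples was 2.58 times that within them, and scaling of whole arrays by a ratio of 2.13 over all rows after quantile normalization. Repeats of 1 preparation or 1 hybridisation batch cannot be told apart from separate plants, since no label ties a number to a preparation; same-numbered samples of the 2 ages deviated together, with correlations of at least 0.425. If the pairs were repeats, a fit of averaged pairs may be the better count, with 400 calls when the ages are taken as independent and 1060 when the pairs are a block across the ages. The latter leaves 1 residual degree of freedom per row, so its calls lean on the variance that eBayes shares between rows.

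As the numbers were taken to pair the samples, the split by age was set against the splits that part all 4 numbered pairs. These are 8 with the real one, too few for a share under 0.05. The real split called 1337 rows and the highest of the other 7 called 0 at a limma adjusted p under 0.05, and 80 at an unadjusted p under 0.05. Of all 35 splits of the 8 samples into 4 and 4, only the real one, 1 split, gave as many rows, but most of the others put both samples of a number into 1 group, and every other split leaves the age difference in the spread within its groups. The highest of the others called 50 rows and was the one that sets samples 1 and 2 of both ages against samples 3 and 4. With samples 1 and 2 alone 1273 rows were called between the ages, and with samples 3 and 4 alone 1414. These fits use only the spread within such a pair of samples. Deviations shared by a pair can therefore count as age differences in them. A check for single samples far from the rest of their age tested 70 groups and found 0. As samples 1 and 2, and samples 3 and 4, lie close together, this check could rarely single out a sample here, and it does not show that none stands apart.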
